A study of Mus musculus with 16 samples.

How the data were processed

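Gene expression was measured on Affymetrix arrays in 16 libraries of sorted olfactory mucosa cells from S100a5-tauGFP mice, which carry a green fluorescent protein (GFP) reporter tied to S100a5. Per the labels, 24 mice were kept singly for 40 h in chambers of clean air, and from 26 h on received short pulses (10 s every 20 min) of either filtered air, the vehicle, or a mixture of isoamyl acetate and whiskey lactone. Cells of 3 mice were pooled and sorted for GFP, and labelled RNA was made from 50 to 100 ng of total RNA. The 24 mice made 8 pools of 3, 4 per treatment, so the pair of libraries with the same treatment and number came from the same mice.

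The authors deposited one table of log2-scale values, made with Affymetrix Expression Console per the submitters' processing notes. The version, the summarization method and the genome build are not given in the sources used here. The values ran from 1.69 to 19.4. The upper end lies above the limit of 16 on the log2 scale for a 16-bit scanner, so a step of unknown form widened the range; differences are given on the deposited log2 scale and not as folds. Library medians over the whole table lay between 6.13 and 6.45. Arrays have no read depth, and the number of arrays limits the precision. Of 28846 probe sets, 6640 carried control identifiers, 19572 were listed with 1 gene symbol, 0 with several, and 2634 were without a listed gene. For genes with several probe sets the one with the highest mean over all 16 arrays was used, which left 19505 genes; 55 genes had more than 1 probe set. Symbols came from the platform annotation given with the data, and coordinates are not given because the build is not stated. Names of receptor families were taken from a RefSeq gene table of assembly GRCm38.p6. The 5222 probe sets whose identifiers name them as negative had a median of 5.45 and a 95th percentile of 9.56, so they did not mark a clean background; 970 of the 1095 receptor genes had a mean above their median.

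Groups followed the sample titles. In all 16 samples the title and the cell type tag named opposite fractions, and the text therefore writes "titled GFP+" and "titled GFP-". If the tags were right, every difference between fractions would change sign, and the odor comparisons of the fractions would change places. Libraries are named by treatment, titled fraction and replicate number. No sample was moved to another group. The 2 libraries of vehicle pool 3 lay with the opposite fraction under either label. Each result is therefore given for all 16 arrays as labelled and for the 14 arrays without that pool. The second set was chosen after the values were seen.

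Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), in 1 model with a mean for each of the 4 groups and no block. P-values were adjusted by Benjamini-Hochberg over the 19505 genes, with a threshold of 0.05; "adjusted p" means this throughout. Errors of differences are limma standard errors. Comparisons were odor against vehicle in each titled fraction, titled GFP+ against titled GFP- in each treatment, and the difference between those fraction differences. Receptors (1080 odorant and 15 trace amine-associated genes) were also counted with p-values adjusted over the list alone. Lists of genes were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and Benjamini-Hochberg was applied over the lists within a comparison; lists with fewer than 4 measured genes were counted only. Comparisons of few values used exact permutation tests.

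Before the data were examined, the tests, the alternatives, the lists and the rule for named genes were fixed. The rule named S100a5, and the 6 largest positive and 6 largest negative differences among called genes other than receptors whose 2 groups did not overlap. It also named the 10 receptors with the smallest p in the difference of fraction differences, up to 15 receptors that passed both there and in odor against vehicle for titled GFP+, and up to 3 members of each list by p. Predicted or unnamed loci were counted and not named. For the difference of fraction differences, "did not overlap" referred to the values per pool. The rule was applied again to the 14 arrays. The lists covered cell types (mature and immature olfactory sensory neurons, globose and horizontal basal cells, sustentacular cells, Bowman gland, microvillar and ionocyte-like cells, ensheathing glia, ciliated cells, myeloid, lymphoid, red blood, endothelial and fibroblast cells), genes raised or lowered by olfactory neuron activity, immediate early genes, heat shock, receptor choice and unfolded protein response, olfactory transduction, ciliary transport, axon guidance, synaptic vesicles, xenobiotic metabolism, apoptosis and p53, guanylyl cyclase D neurons, ribosomal proteins, oxidative phosphorylation, and odorant, trace amine-associated and vomeronasal receptors.

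A fraction score placed each library between the mean of the odor libraries titled GFP- (0) and that of the odor libraries titled GFP+ (100), along the difference of those means over 19505 genes. Odor libraries define this score, so only the vehicle libraries are placed by it independently. The model was tested on simulated data for odor against vehicle in titled GFP+ over 19505 genes. With the spread of all 16 arrays, 67 of 100 genes changed by 1 on the log2 scale and 92 of 100 changed by 2 were recovered, with 8 false calls; with the spread of the 14 arrays these were 62 and 98, again with 8 false calls.

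Fractions of a pool share mice. Deviations from group means correlated within all 4 odor pools (r from 0.127 to 0.253 across genes) and ran from -0.754 to -0.0645 in the 4 vehicle pools, or from -0.0221 to 0.287 without pool 3. Values with the pool of mice as a block are given beside results where that changed the call of a list or named gene, or moved a count by more than 1.5 times. Library correlations over genes lay between 0.946 and 0.995, and 0 pairs of libraries were identical. Alternatives were quantile normalization, centring of arrays on their medians, filters on dim probe sets, eBayes with trend and robust settings, array weights, tests over every probe set, fits of the 2 compared groups alone, both replicate blocks and leaving out each library.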

Results

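The assay sorts olfactory mucosa cells of S100a5-tauGFP mice by reporter signal, and asks which odorant receptor transcripts move into the GFP+ fraction after an odor. S100a5, a calcium-binding protein of olfactory sensory neurons, is induced by neuronal activity, so GFP marks neurons that were recently active. Mice received a mixture of isoamyl acetate and whiskey lactone or filtered air. Each treatment had 4 pools of 3 mice, each pool gave a fraction titled GFP+ and a fraction titled GFP-, and each fraction was measured on 1 array, which made 4 groups of 4 libraries. The table gave 19505 genes, among them 1095 olfactory receptor genes with a median level of 8.71 on the log2 scale against 6.90 for all genes.

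S100a5, which carries the reporter and checks the labels, went against the titles. It was lower in the odor libraries titled GFP+ (15.27 ± 0.24, SD, n = 4) than in those titled GFP- (16.43 ± 0.27, SD, n = 4), a difference of -1.16 ± 0.36 (SE) that missed the threshold over all 16 arrays (adjusted p = 0.0625) and passed it without vehicle pool 3 (adjusted p = 0.000588). By library, S100a5 was 15.39, 15.11, 15.05 and 15.55 in odor replicates 1 to 4 titled GFP+, and 16.04, 16.66, 16.55 and 16.48 in those titled GFP-. In vehicle it was 14.59, 14.92, 16.37 and 15.47 in the libraries titled GFP+, and 16.44, 16.35, 14.99 and 16.27 in those titled GFP-. Vehicle pool 3 therefore ran opposite to the other pools, and without it the vehicle means were 14.99 ± 0.45 (SD, n = 3) and 16.35 ± 0.09 (SD, n = 3). Kirrel2, an adhesion molecule raised by activity, followed the same order in odor, at 14.46 ± 0.51 titled GFP+ and 15.39 ± 0.48 titled GFP- (SD, n = 4 each; limma adjusted p = 0.178 over all 16 arrays and 0.0244 without vehicle pool 3). Omp, the marker of mature olfactory sensory neurons, was 18.52 ± 0.09 and 18.54 ± 0.04 in the odor groups (SD, n = 4 each), close to the top of the table's range.

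**Figure D1:**
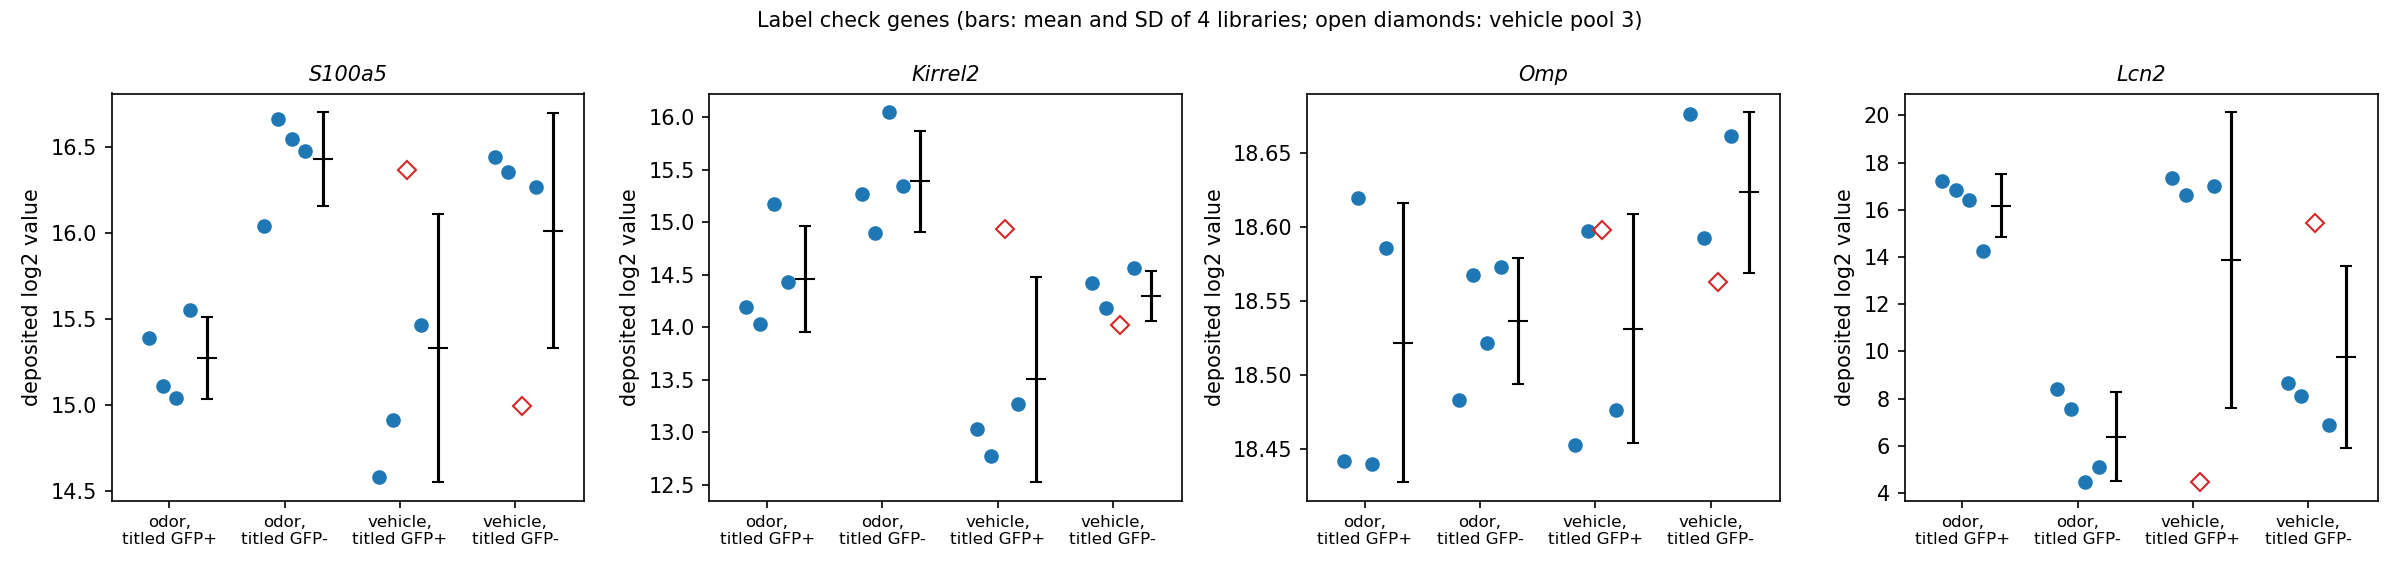
Deposited log2 value (vertical axis) of S100a5, Kirrel2, Omp and Lcn2 in each library of the 4 groups; bars are the mean and SD of 4 libraries and open diamonds are vehicle pool 3. S100a5 in odor averages 15.27 in libraries titled GFP+ and 16.43 in those titled GFP-, and the open diamonds of S100a5 and Lcn2 lie with the opposite titled fraction.

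All genes together placed vehicle pool 3 with the opposite fraction. On the score that runs from 0 (mean of the odor libraries titled GFP-) to 100 (mean of those titled GFP+), vehicle replicates 1, 2 and 4 titled GFP+ scored 99.9 to 114 and those titled GFP- 3.64 to 9.17. Vehicle replicate 3 titled GFP+ scored 1.21 and replicate 3 titled GFP- scored 90.3. Without receptor genes these were 0.782 and 81.3. Odor libraries, which define the scale, ran from 82.0 to 112 and from -3.08 to 4.48. Labels were kept as given, and values without this pool stand beside them.

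**Figure D2:**
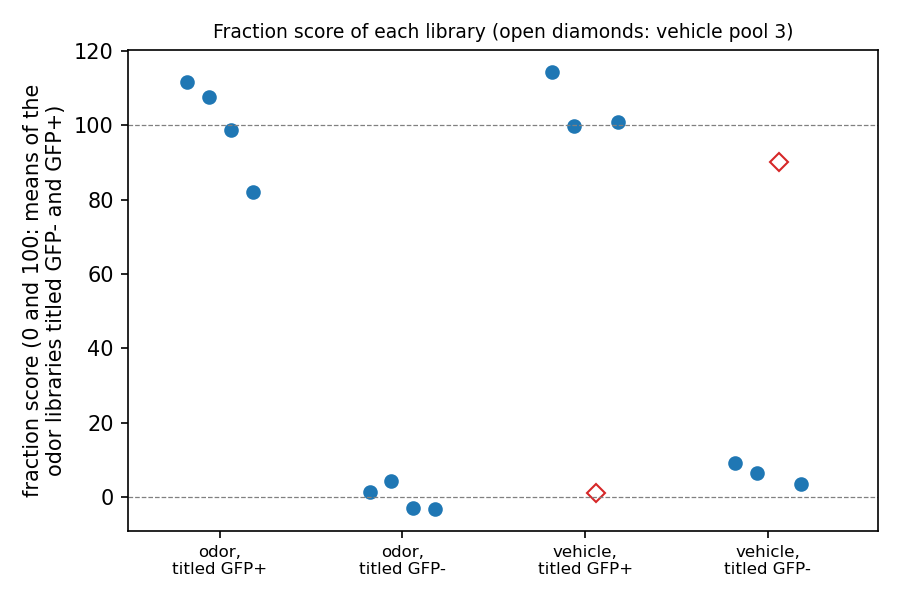
Fraction score (vertical axis, no unit) of each library in the 4 groups, where 0 and 100 are the means of the odor libraries titled GFP- and GFP+; open diamonds are vehicle pool 3. The library of that pool titled GFP+ sits at 1.21 and the one titled GFP- at 90.3.

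In odor-exposed mice, Lcn2, Retnlg and Ngp led the genes that were higher in the fraction titled GFP+ than in the fraction titled GFP-. Lcn2, an iron-scavenging protein of neutrophil granules, was higher by 9.79 ± 2.43 (SE), Retnlg by 9.65, and Ngp, a neutrophil granule protein, by 9.42. S100a8 and S100a9, which form calprotectin, were higher by 8.50 and 7.84, and Ly6c2, a monocyte surface protein, by 8.17 (adjusted p from 0.0286 to 0.0349). Fxyd2, a regulator of the sodium pump, was lower by a log2 difference of -4.02 ± 0.92 (SE), followed by Avp (-2.07), Ptprn (-1.97), Pcp4l1 (-1.82), Rfx4 (-1.68) and Kcng1 (-1.64; adjusted p from 0.0286 to 0.0455). These directions rest on titles that S100a5 went against. Over all 16 arrays 1359 genes differed, 892 higher and 467 lower in titled GFP+. Among them were 409 receptors (201 higher, 208 lower; 671 adjusted over the list alone) and 33 unnamed loci. Without vehicle pool 3 the differences stayed as they were, since that pool enters only the spread, and 2570 genes passed (1675 higher, 895 lower), with 663 receptors (295 higher, 368 lower; 765 adjusted over the list alone). With pools of mice as a block, 2 genes passed over all 16 arrays, Olfr221 and Olfr937, and each of the 12 genes above missed the threshold (adjusted p from 0.161 to 0.162). Without vehicle pool 3 each of these 12 genes passed in limma in every alternative that kept the remaining arrays, that block among them (largest adjusted p = 0.00656, for Kcng1). Those alternatives called from 1668 to 3148 genes. Leaving out odor replicate 1, 2 or 3 of either titled fraction, or odor replicate 4 titled GFP-, left 2 or 3 genes over all 16 arrays, 2 or 3 of them receptors. Leaving out vehicle replicate 3 titled GFP+ gave 2184. Centring arrays on their medians turned the split to 45.5% higher from 65.6% over all 16 arrays, and to 43.8% from 65.2% without pool 3, and moved the median of all genes from -0.08 to -0.24.

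Microvillar, lymphoid, myeloid, sustentacular, Bowman gland, progenitor and immature neuron markers were higher in the odor fraction titled GFP+, while horizontal basal, glial and endothelial markers did not pass; the following counts and adjusted p-values are without vehicle pool 3. All 9 microvillar and ionocyte-like genes were higher (Trpm5 by 3.28, Pou2f3 by 2.25, Cftr by 4.00). Higher too were 8 of 8 genes of the lymphoid list (Ptprc by 4.66, Cd3e by 2.42) and 7 of 11 myeloid genes (Tyrobp by 2.70). So were 7 of 11 sustentacular genes (Krt18 by 3.75, Krt8 by 2.98, Cyp2a5 by 2.08) and 3 of 6 genes of the Bowman gland list (Sox9 by 3.83, Ltf by 6.35, Aqp5 by 1.07). These counts were 9, 8, 8, 8 and 3 adjusted over the list alone, and 8, 4, 6, 3 and 2 over all 16 arrays. Of the 9 globose basal and progenitor genes 7 were higher (Mki67 by 4.65, Kit by 3.61, Insm1 by 1.69), and of 12 immature neuron genes 5 (Gng8 by 4.64, Dpysl3 by 4.05, Gap43 by 2.40). Of the 2 red blood cell genes measured Slc4a1 was higher by 2.46, and of 5 fibroblast genes Dcn by 1.31. Dcn lost its call in 10 fits that left out 1 library and in 5 of 9 other alternatives. None of the 6 horizontal basal, 7 ensheathing glia or 6 endothelial genes passed (limma, 0 each, with 0, 3 and 1 genes at an unadjusted p under 0.05; nearest was Sox10 of glia, 0.69 at an adjusted p = 0.0576), and 1 of 8 ciliated cell genes, Ccdc113, was lower by a log2 difference of -0.87. Camera called the immature, globose, sustentacular, Bowman gland, microvillar, myeloid and lymphoid lists (adjusted p = 0.00238 or less). With an estimated correlation the immature (adjusted p = 0.0102), globose (adjusted p = 0.0102) and microvillar lists (adjusted p = 0.0120) held while sustentacular (adjusted p = 0.162), Bowman gland (adjusted p = 0.196), myeloid (adjusted p = 0.0832) and lymphoid (adjusted p = 0.10) did not. With pools as a block and an estimated correlation these 3 lists missed the threshold too (adjusted p from 0.0584 to 0.0766), and over all 16 arrays no list passed with an estimated correlation (lowest adjusted p = 0.159). With pools as a block over all 16 arrays, 0 genes of any of these lists passed in limma. The same block on the 14 arrays left 9 microvillar, 8 lymphoid, 8 myeloid, 9 sustentacular, 3 Bowman gland, 7 globose and 5 immature neuron genes higher. It left 1 endothelial gene lower where 0 had passed. Members of a list were not shown to come from the cell type that the list names.

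Genes raised by olfactory neuron activity were lower in the odor fraction titled GFP+, against what that title would name, while immediate early genes were higher. On the 14 arrays all 6 activity genes were lower (median -1.05), among them Pcp4l1 (-1.82), Lrrc3b (-1.40) and S100a5 (-1.16); over all 16 arrays 2 of 6 passed, and 6 adjusted over the list alone. Of 25 immediate early genes, transcription factors and regulators induced within minutes of a stimulus, 16 were higher, such as Egr2 by 6.48, Egr1 by 5.59 and Btg2 by 4.78; 17 passed adjusted over the list alone, and 15 over all 16 arrays. Camera called both lists, and with an estimated correlation the activity genes (adjusted p = 0.0162) and immediate early genes (adjusted p = 0.00496) held; with pools as a block the former had an adjusted p = 0.0766. Of 3 genes lowered by activity Epha5 passed, at -0.74. Pools as a block over all 16 arrays left 0 activity or immediate early genes called. On the 14 arrays that block left 6 activity genes lower and 16 immediate early genes higher. Of 14 mature neuron genes 3 were lower (Cidea -1.14, Ano2 -0.51 and Umodl1 -0.38, the last at an adjusted p = 0.0794 with pools as a block), a list that camera called at adjusted p = 0.0337 but not with an estimated correlation (adjusted p = 0.346) or with pools as a block (adjusted p = 0.0512). Markers of immune and supporting cells moved together with these lists.

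Other lists showed smaller or mixed differences in odor without vehicle pool 3. Of 13 xenobiotic metabolism genes 8 were higher, led by Cyp2a5, Cyp1a2 (1.97) and Cyp2g1 (1.52), which sustentacular cells also express; camera's adjusted p of 2.08e-05 became an adjusted p = 0.210 with an estimated correlation, and over all 16 arrays limma called 0 (10 adjusted over the list alone). Of 8 genes of guanylyl cyclase D neurons Pde2a (2.93), Ms4a4c (2.93) and Ms4a6c (2.31) were higher (adjusted p = 0.0507 with an estimated correlation). Synaptic vesicle genes had 4 of 11 lower, or 3 with pools as a block, such as Syn2 (-0.70, camera adjusted p of the list 0.162 with an estimated correlation). Axon guidance genes had 5 of 16 lower and 1 higher (Pcdh10 -1.62, Sema3a 1.01). Olfactory transduction genes had 3 of 14 lower (Pde1c -0.69) and 2 higher (Slc8b1 1.25), or 1 higher with pools as a block. Hspb1 of 8 heat shock genes (0.71), Xbp1 of 12 receptor choice and unfolded protein response genes (0.44) and Fas of 8 apoptosis and p53 genes (0.77) were each the 1 member that was higher. With pools as a block Xbp1 missed the threshold (adjusted p = 0.0788), and heat shock and apoptosis genes had 2 higher each. Fas lost its call in 8 fits that left out 1 library and in 3 of 7 other alternatives, and Hspb1 in 5 and in 2 of 7. Of ciliary transport genes 0 of 12 passed in limma (3 at an unadjusted p under 0.05; Cep290 -0.38, adjusted p = 0.164). Of 60 ribosomal protein genes 0 passed in limma (5 at an unadjusted p under 0.05; Rps26 0.72, adjusted p = 0.0988), with a median of 0.36 that camera called (adjusted p = 0.000223; adjusted p = 0.608 with an estimated correlation). Oxidative phosphorylation had 2 of 75 higher (Cox8b 0.69) and 1 lower (Cox7b2 -0.64, adjusted p = 0.0604 with pools as a block). Vomeronasal receptors had 17 of 319 lower and 0 higher, or 1 higher with pools as a block (camera adjusted p = 0.0243 with an estimated correlation, 0.0766 with pools as a block), 0 higher and 6 lower adjusted over the list alone, at a median of -0.23. Odorant receptors went both ways, with 289 of 1080 higher and 363 lower (334 and 418 adjusted over the list alone), and of 14 trace amine-associated receptors 6 were higher and 5 lower (Taar2 5.29, Taar7a 2.78, Taar4 -2.13). The odorant receptors' median was -0.22 and their mean 0.14, and the trace amine-associated receptors' median -0.62 and mean 0.29, opposite in sign in both lists. Fry, which tests whether a list moves on balance one way without setting it against other genes, gave an adjusted p of 1.17e-07 for immediate early genes and 0.773 for odorant receptors. With pools as a block over all 16 arrays, 2 odorant receptors and 0 genes of the other lists passed. On the 14 arrays it called 299 odorant receptors higher and 374 lower.

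In vehicle mice limma called no gene for the same contrast with labels as given, where vehicle pool 3 ran opposite to the others. S100a5 differed by -0.68 ± 0.36 (SE, adjusted p = 0.553) over all 16 arrays, and by -1.37 ± 0.23 (SE, adjusted p = 0.000560) without that pool. Limma called 0 genes and 0 receptors over all 16 arrays (0 adjusted over the list alone), with 1912 genes at an unadjusted p under 0.05. Camera there called as higher the immediate early list (median 0.91, adjusted p = 4.33e-08), the microvillar (0.75), lymphoid (1.01) and ribosomal lists (0.23; adjusted p = 1.32e-05 each), and the globose list (0.56, adjusted p = 3.33e-05). Myeloid (2.19, adjusted p = 0.00117), sustentacular (0.58) and guanylyl cyclase D genes (0.56; adjusted p = 0.00224 each) followed, with activity genes (-0.74, adjusted p = 0.00347) and vomeronasal receptors (-0.13, adjusted p = 0.0238) lower. None held with an estimated correlation (adjusted p = 0.391 or more). Adjusted over the list alone, 2 guanylyl cyclase D genes, 1 globose gene and 1 red blood cell gene were higher (Ms4a4c, Pde2a, Cdk1 and Slc4a1), and 1 vomeronasal receptor, Vmn1r50, lower. Without pool 3, 2180 genes differed (1533 higher and 647 lower in titled GFP+), including 584 receptors (258 higher, 326 lower; 708 adjusted over the list alone). Lcn2 (9.11 ± 0.90, SE), Retnlg (8.69), Ngp (8.68), Ly6c2 (8.61), Ly6c1 (8.39) and S100a8 (8.34) led the higher genes. Fxyd2 (-4.60 ± 0.29, SE), Avp (-2.32), Nell2 (-1.79), Cntnap5b (-1.78), Pcp4l1 (-1.73) and Caly (-1.68) led the lower ones; all 12 had an adjusted p of 0.00316 or less. By list, 9 of 9 microvillar genes (Ascl3 3.42), 7 of 11 myeloid genes (Tyrobp 3.58) and 7 of 8 genes of the lymphoid list (Ptprc 4.84) were higher. So were 5 of 9 globose genes (Mki67 5.52) and 15 of 25 immediate early genes (Egr2 6.09), while 5 of 6 activity genes were lower (Lrrc3b -1.68). With pools as a block 6 lymphoid and 7 globose genes were higher. Of these lists the globose, microvillar, activity and immediate early lists, and the immature neuron list (4 of 12 higher, Gng8 4.71), held with an estimated correlation (adjusted p = 0.0152 or less), whereas myeloid and lymphoid each had an adjusted p = 0.136. With pools as a block, the immediate early list alone of these 5 held, the others lying between 0.0647 and 0.109. The mature neuron list, 2 of 14 lower, was called by camera (adjusted p = 0.0392, or 0.386 with an estimated correlation) but not with that block (adjusted p = 0.0504). Over all 16 arrays the block brought in the apoptosis and p53 list (camera adjusted p = 0.0751 without it, 0.0279 with it). With an estimated correlation that list did not pass (camera adjusted p = 0.391 without the block, 0.602 with it). Among other lists without pool 3 the block raised the higher genes of xenobiotic metabolism to 7 from 3, of apoptosis to 2 from 1 and of ribosomal proteins to 1 from 0. It lowered those of olfactory transduction to 1 from 2. Lower genes went to 3 from 1 for oxidative phosphorylation, to 5 from 8 for vomeronasal receptors, to 3 from 2 for ciliated cells and to 0 from 1 for synaptic vesicles (Syn2 -0.60, adjusted p = 0.0509). Leaving out vehicle replicate 3 titled GFP+ alone gave 1163 genes and 212 receptors (470 adjusted over the list alone), and replicate 3 titled GFP- alone 19 and 10 (418). Centring arrays turned the share of higher calls without pool 3 to 56.4% from 70.3%. These directions, too, go by titles that S100a5 went against.

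Receptors sorted into the same titled fractions in both treatments. On the 14 arrays without vehicle pool 3 the odor and vehicle contrasts share no array, and over the 1095 receptors their log2 differences correlated at r = 0.977 (Spearman's rho 0.965; across genes, which are not independent replicates). Both contrasts called 551 receptors, 243 higher and 308 lower in titled GFP+ and 0 in opposite directions, against 69.5 and 110 for independent lists. Among the 18410 other genes r was 0.921, and 1231 were called in both, 1085 higher and 146 lower, against 95.6 and 9.19 for independent lists. Calls of both contrasts use the same spread of each gene, taken from all 14 arrays. The numbers for independent lists are therefore only a rough guide.

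Few receptors were called for a change of fraction difference with odor, which the simulated data did not cover, and the clearest was Olfr221. Its level in odor was 8.57 ± 0.76 titled GFP+ and 12.88 ± 0.20 titled GFP- (SD, n = 4 each), while in vehicle both fractions lay near each other (10.47 ± 0.72 and 10.25 ± 0.67, SD, n = 4 each). The difference of fraction differences was -4.53 ± 0.57 (SE, adjusted p = 0.0182), and -4.96 ± 0.55 (SE, adjusted p = 0.00417) without vehicle pool 3. Olfr937 followed at -2.02 ± 0.38 (SE, adjusted p = 0.515) and, without pool 3, -2.08 ± 0.26 (SE, adjusted p = 0.00927), and Olfr170 at -1.79 ± 0.32 (SE, adjusted p = 0.459) and -2.02 ± 0.32 (SE, adjusted p = 0.0891). Exact permutation of the 8 pools gave p = 0.0286 for each of the 3, the smallest that 70 arrangements allow, unadjusted for the choice of receptors. Olfr871, Olfr1168, Olfr94 and Olfr111 had the same p in this test, so it does not set the 3 apart. The negative sign places odor's effect on these receptors lower in the fraction titled GFP+ than in the fraction titled GFP-, and since titles and tags conflict, the latter is tagged GFP+.

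**Figure D3:**
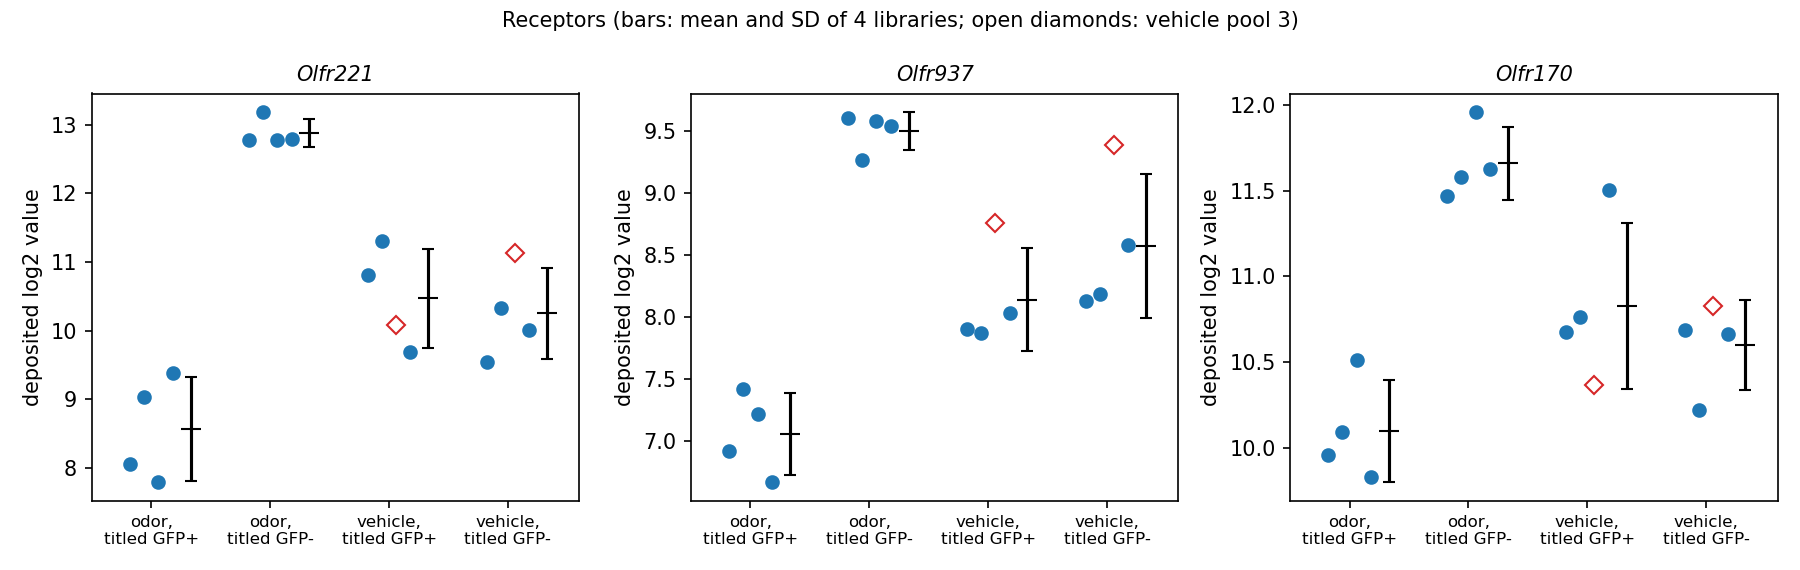
Deposited log2 value (vertical axis) of Olfr221, Olfr937 and Olfr170 in each library of the 4 groups; bars are the mean and SD of 4 libraries and open diamonds are vehicle pool 3. Olfr221 in odor averages 8.57 in libraries titled GFP+ and 12.88 in those titled GFP-, against 10.47 and 10.25 in vehicle.

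Over all 16 arrays 1 gene, Olfr221, passed this test of the difference, and 3 receptors passed adjusted over the list alone (Olfr221, Olfr170 and Olfr937). Without vehicle pool 3, 2 genes passed, Olfr221 and Olfr937, and again 3 receptors adjusted over the list alone. The other receptors among the 10 smallest p over all 16 arrays did not pass: Olfr871 (1.06), Olfr765 (-1.32), Olfr1168 (-2.13), Olfr94 (0.93), Olfr832 (1.77), Olfr111 (2.41) and Olfr299 (3.81), each at an adjusted p of 0.999. When pool 3 was left out, Olfr558 (1.59), Olfr615 (1.89) and Olfr305 (-1.26) came among the 10, also not passing. S100a5 changed its fraction difference by -0.48 ± 0.50 (SE, adjusted p = 0.999). With pools of mice as a block limma called 0 genes over all 16 arrays (512 at an unadjusted p under 0.05; Olfr221 adjusted p = 0.269, in a range of 0.00417 to 0.269 over the alternatives), and 1 on the 14 arrays, where Olfr221 ranged from 0.00382 to 0.0350 and the block ended the call of Olfr937 (-2.08 ± 0.27, SE, adjusted p = 0.130); 5 receptors then passed adjusted over the list alone. Over all 16 arrays the call of Olfr221 was also lost, and limma called 0 genes, when any 1 of odor replicates 1 or 3 of either fraction, odor replicates 2 or 4 titled GFP-, vehicle replicates 1, 2 or 4 titled GFP- or vehicle replicate 1 titled GFP+ was left out (adjusted p from 0.0515 to 0.0789). Without vehicle replicate 3 titled GFP- 2 genes passed. Counting receptors, 1 passed adjusted over the list alone without odor replicates 1 or 4 titled GFP+, odor replicates 3 or 4 titled GFP- or vehicle replicates 1 or 2 titled GFP-. On the 14 arrays Olfr221 passed in every such fit. Olfr937 missed the threshold without vehicle replicate 1 titled GFP- (adjusted p = 0.0597), replicate 2 titled GFP- (0.0575) or replicate 4 titled GFP+ (0.0589). Its adjusted p ranged from 0.00416 to 0.130 across the other alternatives. With odor replicate 2 titled GFP- left out of them, 5 receptors passed adjusted over the list alone. Camera called 11 lists over all 16 arrays, with microvillar and myeloid genes lowest (adjusted p = 0.000130 each; adjusted p = 0.468 with an estimated correlation), of which the activity list missed the threshold with pools as a block (adjusted p = 0.107). On the 14 arrays it called oxidative phosphorylation alone (adjusted p = 0.0181; adjusted p = 0.980 with an estimated correlation).

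Within the fraction titled GFP+, odor against vehicle gave no called gene with labels as given. Limma called 0 of 19505 genes and 0 receptors (0 adjusted over the list alone), with 908 genes at an unadjusted p under 0.05. Without vehicle pool 3, 7 genes passed: Pcdh10, a protocadherin of olfactory axons, was higher after odor by 2.15 ± 0.32 (SE), Lrrc3b, of the activity list, by 1.41 ± 0.22 (SE), Fam161b by 1.19, Ifit1bl2 by 1.07, Fhad1 by 1.06 and Lrrc1 by 0.82, and Wee1, a cell cycle kinase, was lower at -1.10 ± 0.17 (SE; adjusted p from 0.0375 to 0.0446). No receptor passed (limma, 0; 0 adjusted over the list alone; 64 at an unadjusted p under 0.05), with Olfr221 at -2.03 ± 0.39 (SE, adjusted p = 0.111). The activity list was called by camera (adjusted p = 0.00545; adjusted p = 0.368 with an estimated correlation), with 1 of 6 higher, or 3 adjusted over the list alone. Camera also called ribosomal proteins, lower at a median of -0.22 (adjusted p = 0.00545; adjusted p = 0.954 with an estimated correlation), axon guidance, higher (adjusted p = 0.0132; adjusted p = 0.635 with an estimated correlation), and ciliary transport, higher (adjusted p = 0.0477; adjusted p = 0.368 with an estimated correlation). The myeloid list had a median of -0.74 (camera adjusted p = 0.0519), and both red blood cell genes were lower adjusted over the list alone. Over all 16 arrays camera called the Bowman gland, microvillar and axon guidance lists (adjusted p = 0.813 each with an estimated correlation). If the tags were right, this would be the comparison within GFP- cells. Leaving out 1 further library ended these calls in several cases, with 0 genes left without odor replicates 2 or 3 titled GFP+, odor replicates 2 or 4 titled GFP-, or any 1 of vehicle replicates 1, 2 and 4 titled GFP+. There was 1 gene without odor replicates 1 or 4 titled GFP+, 3 without vehicle replicates 2 or 4 titled GFP- and 4 without vehicle replicate 1 titled GFP-. Of receptors, 1 passed without odor replicate 1 of either fraction; adjusted over the list alone, 1 passed without either of these or odor replicate 4 titled GFP+, 2 without vehicle replicate 1 titled GFP+ and 4 without vehicle replicate 4 titled GFP+. Over all 16 arrays, 3 genes passed without vehicle replicate 3 titled GFP+.

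Within the fraction titled GFP-, Camk2n1, an inhibitor of the calcium-dependent kinase CaMKII, and Pcdh10 were higher after odor. Camk2n1 rose by 1.86 ± 0.21 (SE, adjusted p = 0.00408), from 7.56 ± 0.23 to 9.42 ± 0.18 (SD, n = 4 each), and Pcdh10 by 2.87 ± 0.37 (SE, adjusted p = 0.0124), from 8.95 ± 0.79 to 11.82 ± 0.11 (SD, n = 4 each). These were the 2 genes called over all 16 arrays, and 0 receptors passed in limma (48 at an unadjusted p under 0.05, 1 adjusted over the list alone). Camk2n1 was higher after odor in titled GFP+ too, at 8.99 ± 0.27 against 7.76 ± 0.46 (SD, n = 4 each), though limma did not call it there. Its fraction difference did not clearly change with odor (exact permutation of pools, p = 0.143). On the 14 arrays 5 genes passed: Camk2n1 (1.95), Pcdh10 (2.61), Olfr221 (2.92 ± 0.39, SE, adjusted p = 0.0131), Olfr937 (1.20 ± 0.18, SE, adjusted p = 0.0406) and, lower after odor, Pik3ip1 (-0.97, adjusted p = 0.0144); 2 receptors passed adjusted over the list alone, and 5 without odor replicate 2, 4 without vehicle replicate 2 and 1 without vehicle replicate 1, each titled GFP-. Olfr170 reached 1.14 ± 0.23 (SE, adjusted p = 0.132). The activity list was called by camera over all 16 arrays (adjusted p = 0.00153; adjusted p = 0.651 with an estimated correlation), with 0 of 6 passing in limma and 3 adjusted over the list alone. Camera also called markers of other cells and states there, lower for myeloid (median -0.84, adjusted p = 0.00229), immature neuron (-0.41, adjusted p = 0.0112), immediate early (-0.32, adjusted p = 0.0115), xenobiotic (-0.27, adjusted p = 0.0264) and ribosomal genes (-0.22, adjusted p = 0.000508). It called axon guidance (0.16, adjusted p = 0.00532) and vomeronasal receptors (0.09, adjusted p = 0.0115) higher. None held with an estimated correlation (adjusted p = 0.651 or more). When pool 3 was left out it called activity (adjusted p = 0.0130) and axon guidance genes (adjusted p = 0.00169) higher, and myeloid (adjusted p = 0.0123), ribosomal (adjusted p = 5.38e-06) and oxidative phosphorylation genes (adjusted p = 0.00634) lower (adjusted p = 0.501 or more with an estimated correlation). If the tags were right, this would be the comparison within GFP+ cells. Camk2n1 passed in all fits that left out 1 library, while Pcdh10 lost its call over all 16 arrays without any 1 of the 4 odor libraries or vehicle replicates 1 or 4 titled GFP- (adjusted p from 0.0591 to 0.0863), leaving 1 gene, and 5 genes passed without vehicle replicate 3 titled GFP+. Of receptors, 1 passed without vehicle replicate 3 of either fraction, odor replicate 4 titled GFP+ or vehicle replicate 2 titled GFP+. Adjusted over the list alone, 0 passed without odor replicate 2 or vehicle replicates 1 or 4 titled GFP-, and 2 without odor replicate 3 titled GFP- or vehicle replicate 4 titled GFP+. On the 14 arrays 2 genes passed without any 1 of odor replicates 2, 3 or 4 titled GFP-, 3 without vehicle replicate 2 titled GFP-, and 1 without vehicle replicates 1 or 4 titled GFP-. There Olfr221 lost its call without any 1 of odor replicates 2, 3 or 4 or vehicle replicates 1 or 4 titled GFP- (adjusted p from 0.0535 to 0.136). Pik3ip1 lost it without these or vehicle replicate 2 titled GFP- (0.0572 to 0.137), and Pcdh10 without vehicle replicates 1 (0.0878) or 4 (0.0695) titled GFP-. Olfr937 lost it without any 1 library other than odor replicates 2 and 4 titled GFP+ (0.0533 to 0.356), and with the number shared across treatments as a block (adjusted p = 0.115). With that block among them, it missed the threshold in 4 of 9 alternatives that kept all 14 arrays (highest limma adjusted p = 0.233).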

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

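The counts over other splits of the samples and the test of related receptors were set before their results were seen; the other tests of explanations in this part, and all values without vehicle pool 3, were chosen after.

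In vehicle pool 3 the library titled GFP+ scored 1.21 and the one titled GFP- 90.3 on the fraction scale. A single library stood apart from its group of 4 in 61 of 440 groups tested (109 genes and the score). Vehicle replicate 3 was the one apart in 49 of the 61. Chance, at about 1 in 20 groups, would give about 22 for independent genes picked without regard to their values. Many of these genes were named for their fraction differences, in part without this pool. The counts therefore restate the position of the pool and are no separate evidence for it. A poor sort that mixed the fractions would need scores between 25 and 75, and both lie outside (1.21 and 90.3). An exchange of the pool's 2 labels may account for the pattern: 2 of 2 libraries lay within 20 points of the opposite fraction's other vehicle libraries, a bound set after the scores were seen. No biological explanation was tested, and the labels were not changed.

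Genes raised by olfactory neuron activity were lower in the odor fraction titled GFP+, 6 of 6 without vehicle pool 3. Loss of S100a5 transcript from the reporter allele would spare the others, but the 5 other genes had a median of -0.93 with every 95% interval below 0 (highest upper bound -0.33). Such a loss alone thus leaves these 5 genes unexplained, though this restates the 6 of 6 above and is no separate test. Dilution by RNA of other cells would lower mature neuron markers too. The 4 markers compared were those of the list with a mean no higher than that of the highest activity gene (15.8), so levels were not matched gene by gene. The mean of the 6 activity genes was lower than that of these markers, by -0.58 to -0.84 in the 4 odor pools. The genes were few and overlapped (Cidea -1.14; exact permutation p across genes = 0.0429 in odor, 0.0667 in vehicle). Dilution as the whole cause was therefore not decided. It also stays open that the cell type tag and not the title may name the sorted fraction (6 activity genes lower, with medians of 2.70 for myeloid, 1.52 for sustentacular and 2.25 for microvillar genes in titled GFP+). Immediate early genes ran the other way, 16 of 25 higher in titled GFP+, and a biological cause for a reversed reporter was not tested.

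For Olfr221 the fraction difference changed with odor by -4.53 over all 16 arrays and -4.96 without vehicle pool 3, and for Olfr937 by -2.08 without that pool, by the test of the difference itself. A change in the number of these neurons in the tissue, alike in both fractions, would leave no such difference. Without pool 3 and with pools as a block the difference was -4.96 ± 0.46 for Olfr221, -2.08 ± 0.27 for Olfr937 and -2.02 ± 0.25 for Olfr170 (SE). Each passed in limma adjusted over the receptor list (largest adjusted p = 0.00733). The 3 receptors were picked by this same difference on the same arrays. These values therefore restate it and are no separate test of that explanation. The block, which cannot move these estimates, ended the call of Olfr937 over all genes (adjusted p = 0.00927 without it, 0.130 with it; SE 0.26 and 0.27) as residual degrees of freedom fell from 10 to 5, and over all 16 arrays it left Olfr170 (-1.79 ± 0.29, SE) at an adjusted p = 0.0707 over the list. Signal shared with related receptors cannot be told apart, since 1 receptor of the same family had a shift of at least 0.5 times its size (Olfr965, -1.10, for Olfr937), Olfr221 had 0 named relatives, and Olfr170 had 2, the lower at -0.50, and a response of the receptors' neurons to the odor, with the tag naming the sorted fraction, stays a hypothesis. Chance could not be excluded for the 1 gene over all 16 arrays, as 3 of 35 splits of the pools gave as many (highest other 1). Without pool 3 the real split alone of 35 gave 2 genes (highest other 1), a margin too small to exclude chance.

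Other splits of the samples were counted for the remaining comparisons. Between odor fractions the real split alone of 35 gave as many as 1359 genes (highest other 0), and 2570 without pool 3 (highest other 1). Fractions of a pool share mice, and the 8 splits that part every pool are too few for a share under 0.05 (highest other 0, and 1 without pool 3). With pools as a block 2 genes passed over all 16 arrays. Without pool 3 the count with that block lay within 1668 to 3148, the range of the alternatives that kept the remaining arrays. For odor against vehicle in titled GFP- the real split alone of 35 gave as many as 2 genes (highest other 1). Without pool 3 the same held for 5 genes there (highest other 4) and for 7 in titled GFP+ (highest other 3). These margins are too small to exclude chance. Leaving out 1 further library took the 5 genes to as few as 1 and the 7 to as few as 0. For vehicle fractions all 35 splits gave as many as the 0 called, and 1 split called 2540, a structure in which pool 3 stands apart; for odor against vehicle in titled GFP+ all 35 gave as many as 0 (highest other 1). Without pool 3 the vehicle fractions have 10 splits, too few for a share under 0.05, with 2180 genes in the real split and 1 in the highest other.

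The gap of 1 library to its nearest neighbour, as a share of its group's range, was large for these genes. In odor titled GFP+ it was 0.858 for Chat, 0.840 for Epha5, 0.885 for Kit, 0.891 for Olfr94, 0.850 for Sema7a, 0.851 for Sv2a and 0.947 for Wee1. In odor titled GFP- it was 0.879 for Cftr, 0.888 for Ephx1, 0.833 for Nr4a3, 0.969 for Olfr221 and 0.880 for Trp53inp1. In vehicle titled GFP+, with replicate 3 apart each time, it was 0.905 for Btg2, 0.884 for Dpysl3, 0.892 for Egr1, 0.958 for Egr2, 0.970 for Fcer1g, 0.833 for Gng8, 0.891 for Ifit1bl2, 0.944 for Lcn2, 0.848 for Lrrc1, 0.850 for Ltf, 0.840 for Ly6c2, 0.893 for Lyz2, 0.869 for Ms4a4c, 0.942 for Ngp, 0.912 for Pou2f3, 0.952 for Retnlg, 0.951 for S100a8, 0.952 for S100a9, 0.875 for Trp53inp1, 0.887 for Tyrobp, 0.836 for Wee1 and 0.872 for the fraction score. In vehicle titled GFP-, with replicate 3 apart each time, it was 0.940 for Btg2, 0.893 for Cd3e, 0.929 for Cidea, 0.910 for Egr1, 0.921 for Egr2, 0.957 for Fxyd2, 0.865 for Gng8, 0.901 for Krt18, 0.998 for Krt8, 0.852 for Ltf, 0.949 for Ly6c1, 0.908 for Ly6c2, 0.855 for Neurog1, 0.932 for Nr4a3, 0.854 for Olfr1168, 0.891 for Olfr299, 0.838 for Olfr305, 0.915 for Olfr558, 0.865 for Pcp4l1, 0.907 for Pde2a, 0.911 for Pik3ip1, 0.861 for Ptprc, 0.861 for Ptprn, 0.879 for S100a5, 0.897 for Slc4a1, 0.900 for Trpm5 and 0.936 for the fraction score.

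Of the 2634 probe sets without a listed gene, which no comparison used, 191 differed between odor fractions and 128 between vehicle fractions in the fit of every probe set without vehicle pool 3; among 6640 control probe sets these were 66 and 44.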

How the results depend on the processing

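Values without vehicle pool 3, and all alternatives run on those 14 arrays, were chosen after the data were seen; the other alternatives were planned. The named-gene values followed here leave out receptors outside the difference of fraction differences, except Olfr221, Olfr937 and Olfr170; that limit was set after the wider set was seen, in which 22 of 1559 values of 15 receptors changed sign, 19 of them in vehicle fractions and 0 of them called. Of the values followed over all 16 arrays, 1453 kept direction and side of the threshold, 481 lost the call, 20 gained one and 6 changed sign; without pool 3 these were 3224, 304, 4 and 1. Below, counts are of called genes, with receptors named as such; "list alone" means receptors adjusted over the list alone. The cause of each change was not tested, except that fewer libraries or genes enter by construction. Arrays carry no depth; signal over background limits dim genes, and the control probe sets gave no clean floor.

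Over all 16 arrays, eBayes with trend and robust gave 896 genes and 261 receptors between odor fractions. Array weights gave 2727 and 637 there, 1599 genes, 380 receptors and 614 list alone between vehicle fractions, 3 genes and 3 receptors in the difference of fraction differences and 1 receptor in odor against vehicle titled GFP-. Testing every probe set gave 670 genes and 212 receptors in odor fractions and 1 gene in vehicle fractions. Fitting the 2 compared groups alone gave 2315 and 662 in odor fractions and 1 gene in titled GFP-. The replicate block by pool of mice, whose pairing comes from shared mice, gave 2 genes and 2 receptors in odor fractions and 0 and 0 in the difference (limma, 512 genes at an unadjusted p under 0.05). The replicate block by the number shared across treatments gave 0 and 0 in the difference (580 unadjusted) and 4 genes in titled GFP-. Deviations of libraries with the same number correlated unevenly (r from -0.198 to 0.432 in titled GFP+ and -0.164 to 0.129 in titled GFP-). Without pool 3 these ran from 0.0156 to 0.312 in titled GFP+, where 2 of 3 libraries correlated best with their own number. In titled GFP- they ran from -0.118 to 0.236. A pairing by number in titled GFP+ was therefore not excluded. Centring gave 2 list alone in titled GFP-. Leaving out vehicle pool 3 gave 7 genes in titled GFP+, 2570 and 663 in odor fractions, 2180, 584 and 708 list alone in vehicle fractions, 2 and 2 in the difference, and 5 genes, 2 receptors and 2 list alone in titled GFP-.

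Without vehicle pool 3, odor against vehicle in titled GFP+ gave 4 list alone with quantile normalization, 2 genes and 5 list alone with centring, 14 genes above the median level, 21 with array weights, 0 over every probe set (limma, 1885 unadjusted), 0 with the 2 groups alone (1421 unadjusted), and 1 gene and 1 list alone with the replicate block by number. Odor fractions gave 1668 genes above the median level. Titled GFP- gave 1 receptor with trend and robust, 16 genes with array weights, 3 genes and 0 receptors over every probe set, 3 genes and 1 receptor with the 2 groups alone, and 1 receptor with the replicate block by number. The difference gave 1 gene, 1 receptor and 5 list alone with the replicate block by pool, and 1 and 1 with the block by number. Blocks changed no other count by more than 1.5 times.

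Leaving out 1 library at a time over all 16 arrays gave 0 to 3 genes in titled GFP+, 2 to 2184 genes and 2 to 573 receptors in odor fractions, 0 to 1163, 0 to 212 and 0 to 470 list alone in vehicle fractions, 0 to 2 genes, 0 to 2 receptors and 1 to 3 list alone in the difference, and 1 to 5 genes, 0 to 1 receptors and 0 to 2 list alone in titled GFP-. Without pool 3 it gave 0 to 10 genes, 0 to 1 receptors and 0 to 4 list alone in titled GFP+, 1 to 3 genes, 1 to 3 receptors and 3 to 5 list alone in the difference, and 1 to 6 genes, 0 to 2 receptors and 1 to 5 list alone in titled GFP-. The fraction contrasts moved less there, with 2043 to 2609 genes and 609 to 669 receptors in odor fractions. Vehicle fractions gave 1644 to 2267 genes and 490 to 588 receptors. S100a5 in titled GFP+ ranged from -0.31 to 0.29, changing sign to 0.0161 without odor GFP+ replicate 3, and to 0.29 without vehicle GFP+ replicate 3 or without pool 3; its change of fraction difference turned to 0.21 without pool 3, and there to -0.0281 with array weights. Olfr221 between vehicle fractions ranged from -0.0584 to 0.51, turning to -0.0144 without vehicle GFP- replicate 1 and -0.0584 without vehicle GFP+ replicate 2.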

Other observations

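All tests in this part were chosen after the result was seen.

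Class I odorant receptors, the family that mammals share with fish, were set against class II receptors by family name, without vehicle pool 3. Of 1080 odorant receptors 120 were class I, 941 class II and 19 had no family name. The hypothesis that class I receptors sit more in one fraction was not borne out. Their median difference between titled GFP+ and titled GFP- was -0.10 in odor against -0.23 for class II (permutation p = 0.534, 0.534 adjusted over 2 tests), and -0.40 against -0.23 in vehicle (permutation p = 0.469, 0.534 adjusted). Fewer class I receptors were called at all, 49.2% against 61.5% in odor (Fisher's exact test, p = 0.0101) and 42.5% against 54.5% in vehicle (p = 0.0150; both 0.0150 adjusted over 2 tests); genes are not independent replicates. Among 10 receptor pseudogenes 2 were called between odor fractions and 4 between vehicle fractions.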
